A study of Arabidopsis with 36 samples.

How the data were processed

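The series holds 36 RNA sequencing libraries from Arabidopsis seedlings grown for 11 days, all labelled as mock-treated. Per the labels' protocols, RNA was purified with a column kit and made into strand-specific libraries after removal of ribosomal RNA. The samples come from 4 lines: wild type (Col-2), an AtYchF1 overexpressor, an AtYchF1 knockdown mutant and an AtY34 overexpressor. From each line 3 kinds of RNA were sequenced, namely total RNA and the RNA of light and of heavy polysomes, with 3 libraries per line and fraction. In polysome profiling an extract is spun through a density gradient, so that mRNAs carrying few ribosomes (light polysomes) part from those carrying many (heavy polysomes). What AtY34 encodes is not given in the sources used here, so whether it is made from AtYchF1 is unknown.

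The values deposited by the authors are TPM (each transcript's length-scaled share of a library) per gene and TPM per transcript. Each TPM column sums to the same total over nuclear, plastid and mitochondrial loci. Per the submitters' processing notes the tools were FastQC, MultiQC and STAR, without versions, and the genome build was TAIR10. The name of the deposited TPM tables contains salmon; no other step of the quantification is recorded. TPM keep no read number, so the depth of each library is unknown and no count model was used. The gene table lists 33035 loci, of which 32801 are nuclear, 114 plastid and 120 mitochondrial, and the transcript table lists 41086 transcripts. Gene symbols and neighbours came from a gene table of the TAIR10.1 assembly, in which 28446 loci were matched.

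Only the columns of wild type and of the AtY34 overexpressor could be tied to samples by their names, which gives 18 libraries in 6 groups of 3. A further 18 sample columns of the gene table and 54 of the transcript table carry names that match no single label; 36 of the latter have names of no sample in the series. They were not used, so comparisons with the AtYchF1 overexpressor and the knockdown mutant, and the overlap between lines, are not analysed here. The scaling, the filter and the fits had been set for 36 libraries before the data were examined and used 18. Nothing in the labels says whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. None of the 153 pairs of libraries held identical values, and the highest correlation of log2 TPM between a pair was 0.934.

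Nuclear TPM were divided by a factor per library, the median ratio to the geometric mean over the 9431 nuclear genes with TPM of at least 1 in all 18 libraries ("scaled TPM" below). The 20171 nuclear genes with TPM of at least 1 in at least 3 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(scaled TPM + 1), with 1 mean per group and a mean-dependent prior for the variance. All 18 libraries shared 1 estimate of the spread, with 12 residual degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each comparison, and the threshold was an adjusted p of 0.05. Fold changes are on the log2(scaled TPM + 1) scale, which understates the change of low genes. The change between fractions was compared between lines as an interaction in the same model. An exact 0 was common at low levels: 42.0% of values were 0 among genes with a mean TPM from 1 to 2, and 6.48% from 5 to 10. A gene at 0 in a whole group is therefore given as listed at 0, without a fold change.

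The genes named were chosen by a rule set before the data were examined. It took genes past the threshold with a symbol, a mean of at least 5 scaled TPM in a group compared and no overlap between the libraries compared, by size of change: up to 15 in each direction for heavy polysomes against total RNA in wild type, 10 for the AtY34 line against wild type in total RNA and 5 elsewhere. Where none passed, the 3 with the smallest p are given as not passing, and AtYchF1 is always given. Because this rule left out genes without a symbol and most abundant genes, 61 further gene and comparison pairs were chosen after their values were seen; each is named as such.

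Gene lists numbered 35: 28 written by locus and 7 formed by a rule on gene names. They covered photosynthesis (light-harvesting proteins, photosystem subunits, Calvin cycle and photorespiration, chlorophyll synthesis), protein synthesis and turnover (cytosolic and organellar ribosomal proteins, initiation factors, elongation and release, conserved upstream reading frames, proteasome), histones, stress and defence, hormones and nutrition, growth, the clock, and markers of seed, root, vascular tissue, flower and pollen, and guard cells and epidermis. The lists were fixed before the data were examined, except for 46 corrections: loci whose reference names showed another kind of protein were removed from lists formed by rule, and organellar ribosomal proteins were moved out of the cytosolic list; these were made after a first look at the leading genes and before any list was tested. A further 9 entries whose locus and symbol disagreed were dropped. Lists were tested with camera from limma (preset correlation 0.01), adjusted over 245 pairs of list and comparison; camera with an estimated correlation and fry, which tests whether a list's genes move one way, were run beside it. Use of isoforms was tested with diffSplice from limma (Simes) on 6398 transcripts of 2972 genes. The share of TPM on organellar loci was compared with exact two-sided permutation tests.

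The tests were tried on simulated data for the real genes. For heavy against light polysomes in wild type, 3 of 100 genes changed 2-fold and 36 of 100 changed 4-fold were recovered, and 8 of 47 calls were unchanged genes. For the AtY34 line in heavy polysomes 11 of 46 calls were unchanged genes. For the interaction in heavy over total 0 of 100 genes changed 2-fold and 3 of 100 changed 4-fold were recovered, and for heavy over light 0 and 16 of 100. Isoform shifts of 4-fold were recovered in 0 of 100 transcripts and of 16-fold in 37 of 100. A list of 20 genes raised by 0.5 log2 had a camera adjusted p of 0.0148 over 35 lists, with 0 unchanged lists called. The simulation shuffled the residuals of each gene separately and so held no correlation between genes. It therefore does not tell how often list calls in the real data are false.

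Alternatives set beforehand were TPM as deposited, quantile normalization, a pseudocount of 0.1, no filter, the replicate number as a block, alone or within line, only the groups compared in the fit, an estimated correlation for lists, transcripts with TPM of at least 5 in at least 3 libraries for isoforms, plastid loci alone for the organellar share, and each library left out in turn. An alternative without organellar ribosomal RNA was also set and is not analysed here, since the reference names no organellar loci. Filters at a mean of 5, 10 and 20 scaled TPM, differences of the organellar share within replicate numbers, and comparisons that pool both lines or all fractions were added after seeing the data, as was a count of genes near the copy of mitochondrial DNA on chromosome 2, whose range of loci was written from general knowledge and not read from the reference. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.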

Results

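Polysome-associated and total RNA of 11-day seedlings were compared between wild type and the AtY34 overexpressor, to ask which mRNAs sit on light or heavy polysomes and which differ between the lines. Each of the 6 groups (2 lines and 3 fractions) held 3 libraries. The gene table gives TPM, so depth per library is unknown; between 16035 and 19398 loci were above 0 in a library, and the scaling factors ran from 0.736 to 1.39. Within a group, log2 values of replicates correlated across genes with r between 0.803 and 0.874. The median standard error (SE) of a log2 fold change between 2 groups was 0.566, and 0.322 for genes with a mean of at least 20 scaled TPM. Levels below are scaled TPM as mean ± SD with n = 3, and adjusted p-values are from limma.

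AtYchF1 (AT1G30580), the gene in the title of the series, was several-fold higher in the AtY34 line in every fraction. In total RNA its level was 42.5 ± 10.3 in wild type and 210 ± 34.5 in the AtY34 line, a 4.93-fold ratio (log2 fold change 2.29, SE 0.25, adjusted p = 1.97e-04). In light polysomes it was 31.1 ± 11.1 against 195 ± 20 (log2 fold change 2.67, adjusted p = 2.66e-05), and in heavy polysomes 35.8 ± 6.11 against 170 ± 9.03 (log2 fold change 2.23, adjusted p = 3.85e-04). Its shift from total RNA to heavy polysomes differed between the lines by -0.06 (SE 0.35, adjusted p = 1). The labels give no locus for AtY34 and do not tell whether it is made from AtYchF1 or whether these columns carry another line's name. The columns of the AtYchF1 overexpressor itself could not be told apart. With only the 6 libraries compared in the fit, the AtYchF1 differences did not pass (adjusted p = 0.11 in total RNA, 0.276 in light and 0.0884 in heavy polysomes).

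**Figure D1:**
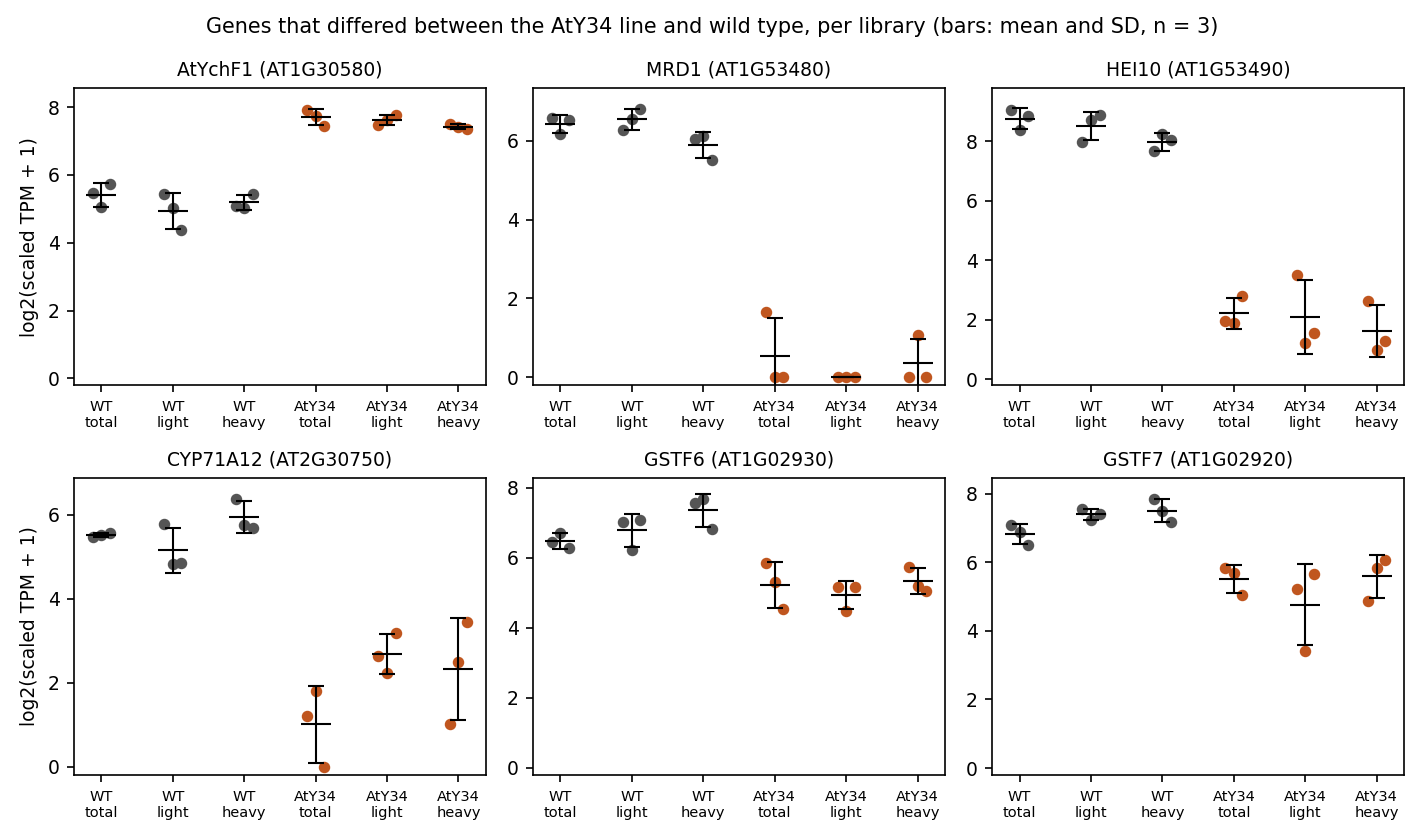
Level of 6 genes as log2(scaled TPM + 1) on the y axis in wild type and the AtY34 line in total RNA, light and heavy polysomes on the x axis; points are libraries, and bars are the mean ± SD of 3 libraries. AtYchF1 lay at a mean of 210 scaled TPM in total RNA of the AtY34 line against 42.5 in wild type, while HEI10 lay at 3.84 against 439.

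Heavy polysomes of wild type were compared with total RNA to find transcripts that ribosomes hold in large or small number. AT1G15405, a non-coding RNA chosen after its values were seen, stood at 222550 ± 25007 in total RNA and at 3622 ± 1150 in heavy polysomes, 61.4-fold lower (log2 fold change -5.99, SE 0.30, adjusted p = 3.29e-09). The spliceosomal U12 RNA fell from 1060 ± 364 to being listed at 0 in all 3 heavy libraries (adjusted p = 3.10e-04), and U2.7, another spliceosomal RNA, from 36 ± 21.2 to being listed at 0. U1.5 fell by 3.83 (SE 0.45, adjusted p = 5.94e-04), from 7654 ± 2888 to 638 ± 552. AT7SL-1, the RNA of the signal recognition particle, fell by 4.92 (SE 0.75, adjusted p = 0.00786). AT2G31141, annotated as protein-coding and chosen after its values were seen, fell by 5.12 (SE 0.34, adjusted p = 2.12e-07).

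PPD5, a protein with a PsbP domain, fell by 2.07 (SE 0.31, adjusted p = 0.00731), from 40.7 ± 11.6 to 8.68 ± 0.750. TLP2, a Tubby-like protein, fell by 1.198 (SE 0.22, adjusted p = 0.0386). STR16, a sulfurtransferase, fell by 1.15 (SE 0.18, adjusted p = 0.0119), and SSR16, a ribosomal protein of an organelle, fell by 1.05 (SE 0.18, adjusted p = 0.0180). CAB1, a chlorophyll a/b-binding protein of the light-harvesting antenna, fell by 1.03 (SE 0.18, adjusted p = 0.0307), from 9363 ± 410 to 4619 ± 737. ELF4-L2, related to the clock gene ELF4, was the 1 gene higher, listed at 0 in the total RNA libraries and at 15.4 ± 3.61 in heavy polysomes (adjusted p = 0.0369). Past the threshold were 26 of 20171 genes, 1 higher and 25 lower, and 18 of the 26 are annotated as protein-coding, AT7SL-1 among them. In all 1989 genes had an unadjusted p under 0.05, where 1009 were due by chance. The same number is due by chance in every other limma comparison of these genes below.

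The median of all genes moved by 0.52 between heavy polysomes and total RNA in TPM as deposited and by 0.05 after scaling; AT1G15405 alone held up to 18.4% of the TPM of a wild-type total RNA library. With TPM as deposited 789 genes passed, 763 of them higher; CAB1, TLP2, STR16 and SSR16 then no longer passed, and neither did they with quantile normalization. With only the 6 libraries compared in the fit 2 genes passed, and 17 passed without wild-type total RNA replicate 3. Of 6 fits with 1 library left out, the call of ELF4-L2 ended in 6, those of CAB1 and TLP2 in 5, that of SSR16 in 4, that of STR16 in 3 and that of U2.7 in 1. A pseudocount of 0.1 ended the calls of CAB1 and AT7SL-1, and no filter those of CAB1 and ELF4-L2.

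Light-harvesting proteins as a list fell in heavy polysomes against total RNA: of 21 members 15 had negative and 6 positive values (median -0.46, camera adjusted p = 7.10e-06; adjusted p = 0.394 with an estimated correlation). Over all genes 1 member, CAB1, fell. Adjusted over the list alone 11 fell and 3 rose, among them CAB2 with a value of -0.86, LHB1B1 with -0.94 and CAB3 with -0.91. The list for the Calvin cycle and photorespiration fell too, with 16 of 21 values negative and a median of -0.22 (adjusted p = 0.00222; adjusted p = 0.446 with an estimated correlation). None of its members passed over all genes. With the list adjusted alone 5 fell and 1 rose, with GAPA at -0.79, RBCS2B at -0.56, RBCS1A at -0.49 and GLDP1, which acts in photorespiration, at 0.49. Cytosolic ribosomal proteins fell (29 of 39 values negative, median -0.22, adjusted p = 0.0228; adjusted p = 0.303 with an estimated correlation). In this list 0 members passed over all genes or adjusted over the list alone. RPS5A had a value of -0.70 and RPS15A of -1.31. The list was formed by a rule on gene names, so ribosomal protein genes whose names did not match are not in it. With TPM as deposited these 3 lists turned to positive directions (adjusted p = 0.874 for light harvesting, 0.0201 for Calvin cycle and photorespiration and 0.478 for ribosomal proteins). With quantile normalization the Calvin cycle list (adjusted p = 0.474) and the ribosomal list did not pass either, nor did the ribosomal list without total RNA replicates 1 or 2 or heavy polysome replicate 2.

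Genes of the endoplasmic reticulum and its stress response rose in heavy polysomes against total RNA, with 14 of 17 values positive and a median of 0.30 (adjusted p = 0.00794; adjusted p = 0.189 with an estimated correlation). None passed over all genes; adjusted over the list alone CRT3, a calreticulin, rose by 1.98, the chaperone BIP1 by 0.84 and the sensor kinase IRE1-1 by 1.72. Without wild-type total RNA replicate 1 the list's adjusted p was 0.0666.

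Light polysomes of wild type differed from total RNA for 21 genes, 11 higher and 10 lower (1895 genes had an unadjusted p under 0.05). UBL5, a ubiquitin-like protein, rose from 172 ± 15.4 in total RNA to 415 ± 48.5 (log2 fold change 1.27, SE 0.17, adjusted p = 0.00344). AT1G07590, chosen after its values were seen, rose from 901 ± 110 to 2480 ± 524 (log2 fold change 1.44, SE 0.20, adjusted p = 0.00473). The same RNAs fell: AT1G15405 by 3.53 (SE 0.30, adjusted p = 1.92e-05), U12 by 7.77 (adjusted p = 0.00473), AT7SL-1 by 5.32 (SE 0.75, adjusted p = 0.00473), U2.7 by 4.48 (adjusted p = 0.0328) and U1.5 by 2.74 (adjusted p = 0.0194). HSFA9, a heat shock factor, was at 16.1 ± 4.95 in total RNA and listed at 0 in light polysomes. LHCB2.1, an antenna protein chosen after its values were seen, fell by 0.82 (SE 0.15, adjusted p = 0.0489). The median of all genes moved by 0.45 in TPM as deposited and by 0.11 after scaling. With TPM as deposited 64 genes passed, 55 higher, and 7 passed without wild-type light polysome replicate 3, which ended the calls of U1.5, U2.7, HSFA9 and LHCB2.1. The LHCB2.1 call ended in 12 of 16 settings, TPM as deposited and quantile normalization among them, that of AT1G15405 with quantile normalization, and those of AT7SL-1 and U2.7 with a pseudocount of 0.1. Of 6 fits with 1 library left out, the calls of HSFA9 and LHCB2.1 ended in 5 and those of U1.5 and U2.7 in 4.

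**Figure D2:**
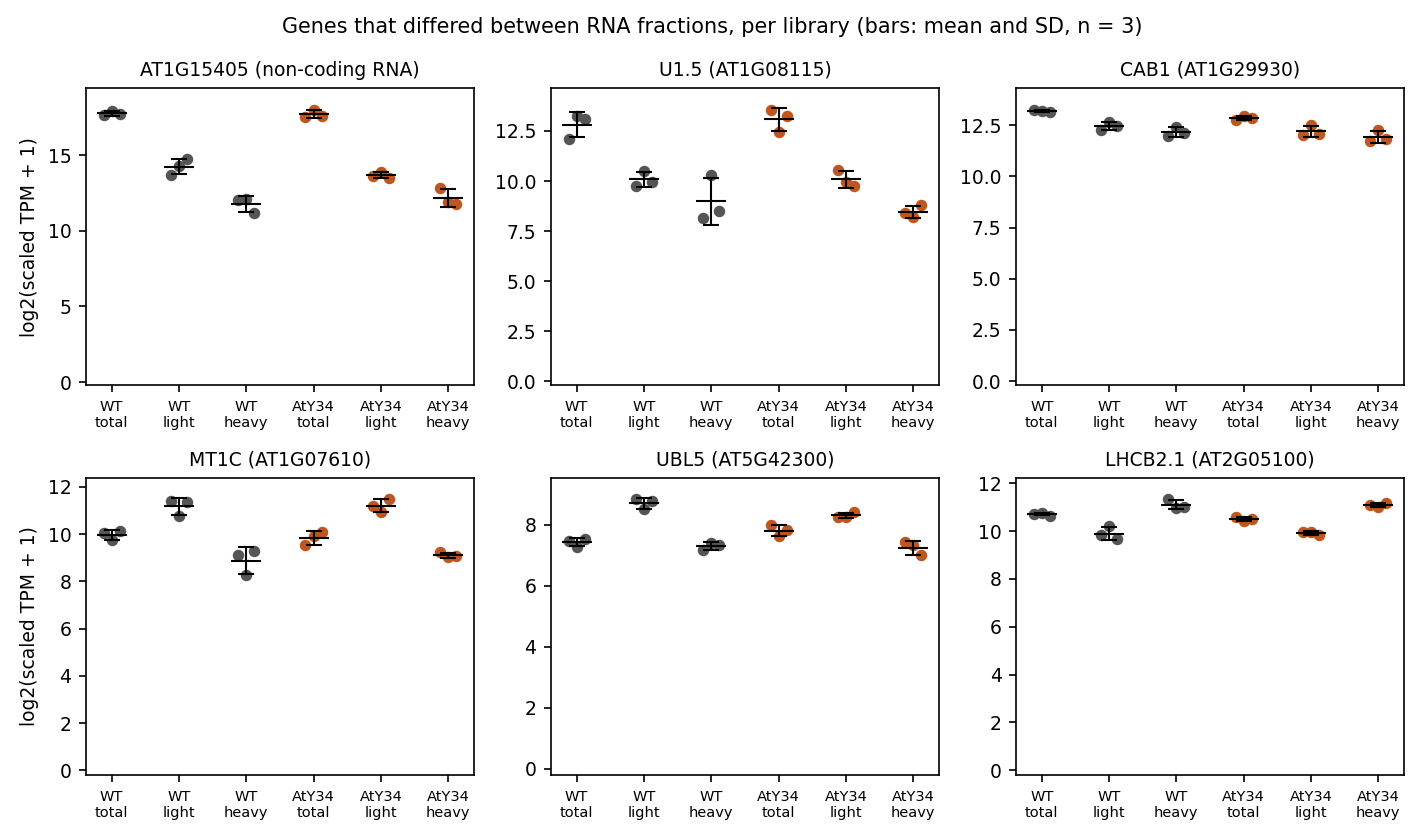
Level of 6 genes as log2(scaled TPM + 1) on the y axis in total RNA, light and heavy polysomes on the x axis for wild type and the AtY34 line; points are libraries, and bars are the mean ± SD of 3 libraries. AT1G15405 stood at 222550, 19960 and 3622 scaled TPM in the 3 fractions of wild type, and LHCB2.1 at 1680, 966 and 2212.

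Heavy against light polysomes asked which transcripts carry many rather than few ribosomes. The genes of this paragraph were chosen after their values were seen, and they do not stand for photosynthesis transcripts at large. Of 21 light-harvesting proteins 17 had negative and 4 positive values in wild type (median -0.15), 2 members rose over all genes, and the list did not pass (adjusted p = 0.755). LHCB2.1 rose from 966 ± 194 to 2212 ± 306 (log2 fold change 1.205, SE 0.15, adjusted p = 9.43e-04) and its relative LHCB2.2 rose by 0.96 (SE 0.13, adjusted p = 0.00141). FED A, a ferredoxin, rose by 1.02 (SE 0.15, adjusted p = 0.00289), DRT112, a plastocyanin, by 1.02 (SE 0.15, adjusted p = 0.00335) and PSBY, a photosystem II subunit, by 1.27 (SE 0.19, adjusted p = 0.00315). GS2, the plastid glutamine synthetase, rose by 1.13 (SE 0.17, adjusted p = 0.00275), and GLDP1, a subunit of glycine decarboxylase, by 0.94 (SE 0.15, adjusted p = 0.00447).

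In the other direction MT1C, a metallothionein, fell from 2371 ± 542 in light polysomes to 493 ± 168 in heavy polysomes, 4.81-fold lower (log2 fold change -2.30, SE 0.25, adjusted p = 1.93e-04). ENODL18, an early nodulin-like protein, fell by 3.06 (SE 0.56, adjusted p = 0.0132), PEX19-2, a peroxisome import factor, fell by 2.999 (SE 0.57, adjusted p = 0.0161), NPSN12, a plant SNARE, by 2.61 (SE 0.48, adjusted p = 0.0131) and PyrD, an enzyme of riboflavin synthesis, by 2.57 (SE 0.47, adjusted p = 0.0131). The rule also gave HSFA9, listed at 0 in light polysomes and at 8.34 ± 4.04 in heavy ones. It further gave AGP30, HSP60-2, PH1 and EMB3119, which rose by 2.63, 2.02, 1.65 and 1.47 (adjusted p between 0.0283 and 0.0471). Chosen after their values were seen, AT1G07590 fell by 2.31 (SE 0.20, adjusted p = 2.77e-05), AT1G56045 by 2.77 (SE 0.26, adjusted p = 4.55e-05), UBL5 by 1.40 (SE 0.17, adjusted p = 5.28e-04) and STR16 by 1.42 (SE 0.18, adjusted p = 9.43e-04). TOM5, of the mitochondrial import machinery, fell by 2.01, and NdhL, of the chloroplast NADH dehydrogenase-like complex, by 1.44. RAPTOR1 and LST8-1, which both bind the kinase TOR, went apart, RAPTOR1 rising by 1.26 (SE 0.27, adjusted p = 0.0305) and LST8-1 falling by 1.58 (SE 0.32, adjusted p = 0.0232).

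This comparison had 193 genes past the threshold, 79 higher and 114 lower, and 2365 with an unadjusted p under 0.05. Quantile normalization gave 117 higher and 114 lower, and TPM as deposited 179 higher and 95 lower. Among the higher genes 11 lay in a range of loci around the copy of mitochondrial DNA on chromosome 2, where reads can be shared with mitochondrial loci, whose share of TPM was 1.93% ± 0.435 in light and 2.72% ± 0.321 in heavy polysomes. With only the 6 libraries compared in the fit 0 genes passed (limma), and leaving out a single library gave counts from 67 without light polysome replicate 3 to 124 without light polysome replicate 2. RAPTOR1, TOM5, AGP30, HSP60-2, EMB3119 and HSFA9 missed the threshold whichever library was left out, LST8-1 in 5 of 6 such fits, PH1 and NdhL in 4, PEX19-2, NPSN12, PyrD and the histones HTB4 and HTB11 in 3 and ENODL18 in 2. The calls of ENODL18 and AGP30 ended with a pseudocount of 0.1, those of AGP30, HSP60-2 and HSFA9 with no filter and that of LST8-1 with TPM as deposited.

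The list of photosystem subunits rose between light and heavy polysomes, with 21 of 28 values positive and a median of 0.26 (adjusted p = 2.34e-05; adjusted p = 0.334 with an estimated correlation, and 0.337 with quantile normalization). Over all genes 2 rose and 1 fell. Adjusted over the list alone 9 rose and 1 fell, with PSBY at 1.27, PSAD-1 at 0.82, PSBQA at 0.67 and PPD5 at -1.67. Histones rose too (13 of 21 values positive, median 0.30, adjusted p = 8.62e-04; adjusted p = 0.135 with an estimated correlation). Over all genes 3 rose, and adjusted over the list alone 5 rose, with HTB1 at 1.13, HTB4 at 0.97, HTB11 at 0.84 and HTA10 at 1.17, all histones of the H2A and H2B kinds. Genes of nitrogen metabolism and response rose (12 of 17 values positive, median 0.48, adjusted p = 0.00794; adjusted p = 0.290 with an estimated correlation). GS2 rose over all genes, and adjusted over the list alone 6 rose and 2 fell, with the nitrogen assimilation genes GLN1.3 at 1.07, ASN1 at 0.68 and GLU1 at 0.67.

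Genes of reactive oxygen metabolism rose in the same comparison (18 of 22 values positive, median 0.31, adjusted p = 0.00306; adjusted p = 0.255 with an estimated correlation). Yet 0 members passed over all genes or adjusted over the list alone; the catalase CAT1 had a value of 1.12 and the peroxiredoxin PRXQ of 0.72. The endoplasmic reticulum list rose (13 of 17 positive, median 0.26, adjusted p = 0.0157; adjusted p = 0.230 with an estimated correlation). BIP2 rose by 1.02 over all genes, and adjusted over the list alone 2 rose, BIP1 being the other. Genes of abscisic acid, salt and drought response rose (17 of 27 positive, median 0.53, adjusted p = 0.0157; adjusted p = 0.446 with an estimated correlation). The dehydrin COR47 rose by 0.90 over all genes. Adjusted over the list alone 3 rose, LTI65 at 1.37 and RD22 at 0.53 among them, and ABI2, a phosphatase, fell with -1.57. Chlorophyll synthesis rose (12 of 19 positive, median 0.26, adjusted p = 0.0298; adjusted p = 0.490 with an estimated correlation). HEMC at 0.95 was the 1 member past the threshold over all genes and adjusted over the list alone. The call of chlorophyll synthesis ended with quantile normalization and without light polysome replicates 1 or 3 or heavy polysome replicate 2. That of abscisic acid response ended without heavy polysome replicate 1 (adjusted p = 0.0822), and that of nitrogen without heavy polysome replicate 2 (adjusted p = 0.0519).

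Comparisons of fractions in the AtY34 line and over both lines were added after seeing the data. Of the 193 genes called between heavy and light polysomes in wild type, 185 had the same sign in the AtY34 line and 154 an unadjusted p under 0.05 there with that sign. In the AtY34 line alone 139 genes passed, 53 higher and 86 lower, and 74 genes passed in both lines with the same direction, where independent lists would share 0.208 higher and 0.486 lower genes. The calls of the lines are not independent, since both rest on 1 estimate of the spread per gene. The values of 0.208 and 0.486 may therefore understate the overlap due by chance. Across 4370 genes with a mean of at least 20 scaled TPM the log2 fold changes of the lines had an r of 0.673 and a rho of 0.705. Over all tested genes r was 0.345 and rho 0.344. Genes are not independent replicates. For heavy polysomes against total RNA 24 of 26 genes had the same sign and 8 passed in both lines. There r was 0.496 across the 4370 genes and 0.181 over all tested genes.

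**Figure D3:**
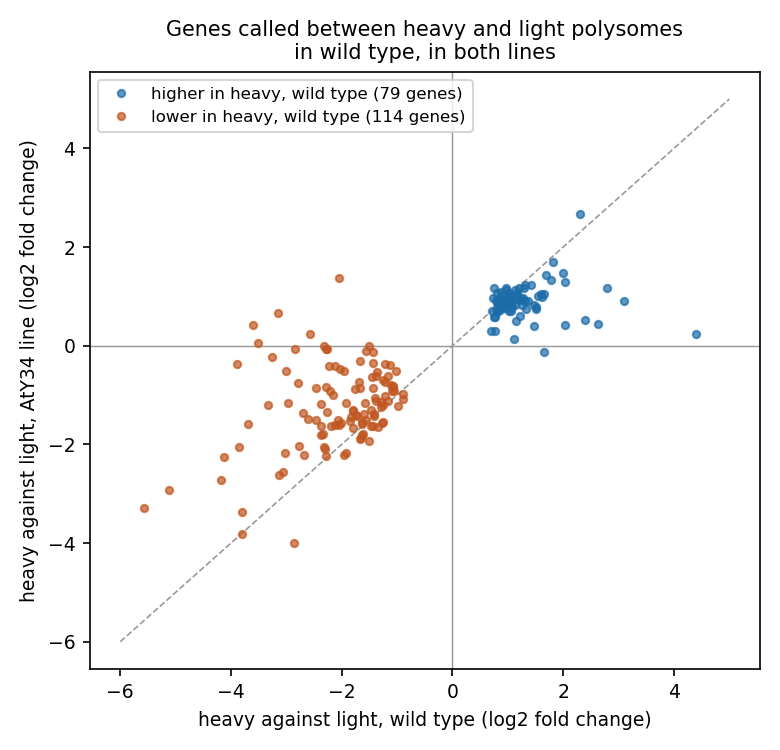
Log2 fold change between heavy and light polysomes in wild type on the x axis and in the AtY34 line on the y axis for the 193 genes called in wild type, 1 point per gene from 3 libraries per group; the dashed line marks equal values. The median in the AtY34 line was 0.90 for genes higher in wild type and -1.21 for genes lower there.

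Over both lines 191 genes passed between heavy polysomes and total RNA, 31 higher and 160 lower. Chosen after their values were seen, TCTP, a growth-related translationally controlled protein, fell by 1.105 (SE 0.15, adjusted p = 0.00145), and CAB1, CAB2 and CAB3 by 0.97, 0.76 and 0.83. GAPA, a glyceraldehyde-3-phosphate dehydrogenase of the Calvin cycle, fell by 0.73, the transcription factor ORA47 by 1.75, the small GTPase ARFA1E by 1.18 and DI19 by 1.14. With TPM as deposited these calls ended except that of ORA47, those of CAB1, CAB2, CAB3 and GAPA with quantile normalization too, and 3579 genes passed, 3494 of them higher. Between heavy and light polysomes 944 genes passed over both lines, 379 higher and 565 lower, with 1024 genes and 463 of them lower after quantile normalization and 675 higher and 406 lower in TPM as deposited. Light polysomes against total RNA gave 92 genes, 47 higher and 45 lower, against 1153 higher and 24 lower in TPM as deposited and 31 higher and 25 lower after quantile normalization.

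Total RNA of the AtY34 line was compared with that of wild type to find transcripts whose level differs between the lines. HEI10 (AT1G53490), named for a RING protein of meiotic crossing-over, fell from 439 ± 101 to 3.84 ± 1.84 (log2 fold change -6.54, SE 0.51, adjusted p = 2.24e-06), and its neighbour MRD1 (AT1G53480) from 85.7 ± 12.8 to 0.719 ± 1.25 (log2 fold change -5.87, SE 0.44, adjusted p = 2.24e-06). The spans of these loci overlap in the TAIR10.1 annotation, so that reads could be shared. CYP71A12, a cytochrome P450 that makes precursors of camalexin, fell from 44.9 ± 1.22 to 1.28 ± 1.25 (log2 fold change -4.51, SE 0.54, adjusted p = 5.91e-04). PFD1, a prefoldin subunit, fell from 30.1 ± 1.29 to 5.14 ± 0.225 (log2 fold change -2.34, SE 0.38, adjusted p = 0.0165), a call that ended in 5 of 6 fits with 1 library left out. In the other fractions PFD1 was not lower in the AtY34 line, at 28.7 ± 6.49 against 24.7 ± 5.29 in light and 18.198 ± 9.65 against 11.3 ± 3.75 in heavy polysomes.

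In this comparison 16 genes passed, 5 higher and 11 lower, and 1639 had an unadjusted p under 0.05. Besides AtYchF1 the higher genes were listed at 0 in wild-type total RNA: GTG1, a G-protein-related membrane protein, at 8.14 ± 3.23 in the AtY34 line (4.76 ± 0.339 against 4.94 ± 2.66 in light polysomes), and, chosen after their values were seen, AT4G35430 at 19.4 ± 6.65, AT1G52347 at 17.9 ± 5.66 and AT3G28760 at 7.41 ± 4.20. In light and heavy polysomes AT4G35430 was listed at 0 in both lines. AT1G52347 had means of 15.2 in light and 3.24 in heavy polysomes of wild type, against 13.4 and 6.63 in the AtY34 line. Those of AT3G28760 were 1.73 and 2.26 in wild type, against 1.43 and 2.12. Among lower genes chosen after their values were seen, AT2G43590, of the chitinase family, fell by 3.87 (SE 0.57, adjusted p = 0.00697) and AT1G26390, of the berberine bridge enzyme family, by 3.24 (SE 0.57, adjusted p = 0.0333). The calls of AT3G28760 and AT1G26390 each ended in 5 of 6 fits with 1 library left out and with TPM as deposited, that of AT3G28760 also with quantile normalization and that of AT1G26390 with a pseudocount of 0.1. Those of GTG1 and AT1G52347 ended without AtY34 total RNA replicate 1. With a pseudocount of 0.1 the count was 24, 12 in each direction, and 1 gene passed with only the 6 libraries compared in the fit.

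The list of seed genes fell in total RNA of the AtY34 line (11 of 14 values negative, median -0.91, mean -1.199, adjusted p = 0.00222; adjusted p = 0.446 with an estimated correlation). Of its members 0 fell over all genes, and adjusted over the list alone SESA2 and SESA1, which are seed storage albumins, fell. SESA1 and SESA2 were listed at 0 in all 9 AtY34 libraries, and without wild-type total RNA replicate 2 the list's call ended. Reactive oxygen metabolism fell (15 of 22 negative, median -0.20, adjusted p = 0.00725; adjusted p = 0.303 with an estimated correlation). STZ, a zinc finger stress regulator, was at -2.29 and GSTF6, a glutathione transferase, at -1.25; these 2 fell adjusted over the list alone and not over all genes. Light-harvesting proteins (19 of 21 negative, median -0.16, adjusted p = 0.0317; adjusted p = 0.724 with an estimated correlation) and photosystem subunits (24 of 28 negative, median -0.17, adjusted p = 0.0298; adjusted p = 0.589 with an estimated correlation) fell as lists with 0 members past the threshold over all genes or adjusted over the list alone. Both calls ended with TPM as deposited and with quantile normalization.

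In light polysomes 7 genes differed between the lines, 1 higher and 6 lower. Those with an unadjusted p under 0.05 numbered 925, fewer than the 1009 due by chance. MRD1 was at 93.3 ± 16.9 in wild type and listed at 0 in all 3 AtY34 libraries, and HEI10 fell by 6.42 (SE 0.51, adjusted p = 3.07e-06). GSTF7, a glutathione transferase, fell from 168 ± 18.7 to 31.7 ± 20.3 (log2 fold change -2.64, SE 0.43, adjusted p = 0.0348); it and GSTF6 are near-identical copies that can share reads. AT1G26390, chosen after its values were seen, fell by 3.44 (SE 0.57, adjusted p = 0.0348). The calls of GSTF7 and AT1G26390 each ended in 5 of 6 fits with 1 library left out and with a pseudocount of 0.1, that of GSTF7 also with TPM as deposited.

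Early wound and touch genes fell as a list in light polysomes (16 of 19 values negative, median -0.56, adjusted p = 8.62e-04; adjusted p = 0.189 with an estimated correlation). It had 0 members past the threshold over all genes or adjusted over the list alone; TCH2, a calmodulin-like protein, had a value of -1.07. Reactive oxygen metabolism fell (14 of 22 negative, median -0.10, mean -0.38, adjusted p = 0.0165; adjusted p = 0.336 with an estimated correlation). GSTF7 fell over all genes, and adjusted over the list alone 3 fell, with GSTF6 at -1.84 and GSTU19 at -0.82, all glutathione transferases. Its call ended without AtY34 light polysome replicate 2. Seed genes (11 of 14 negative, median -0.91, adjusted p = 0.0467; adjusted p = 0.628 with an estimated correlation) and light-harvesting proteins (18 of 21 negative, median -0.14, adjusted p = 0.04996; adjusted p = 0.746 with an estimated correlation) fell with 0 members past the threshold, over all genes or adjusted over the list alone. Those calls ended under several settings, light harvesting among others with TPM as deposited and seed genes with quantile normalization.

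Heavy polysomes of the AtY34 line differed from wild type for 4 genes. Those with an unadjusted p under 0.05 numbered 901, fewer than the 1009 due by chance. Beside AtYchF1, HEI10 fell by 6.35 (SE 0.51, adjusted p = 3.66e-06), MRD1 by 5.53 (SE 0.44, adjusted p = 3.66e-06) and CYP71A12 by 3.62 (SE 0.54, adjusted p = 0.0146), from 61.9 ± 17.5 to 5.17 ± 4.44. The CYP71A12 call ended without wild-type heavy polysome replicates 1 or 2 or AtY34 heavy polysome replicate 1 and with a pseudocount of 0.1, and 8 genes passed without AtY34 heavy polysome replicate 2.

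Genes of indole glucosinolate and camalexin synthesis fell as a list in heavy polysomes (13 of 17 negative, median -0.52, adjusted p = 1.73e-05; adjusted p = 0.189 with an estimated correlation). CYP71A12 fell over all genes. Adjusted over the list alone CYP71A13, which also acts in camalexin synthesis, fell by 1.31 beside it, while CYP81F2, of indole glucosinolate synthesis, had a value of -1.80. Genes of pattern-triggered immunity fell (15 of 20 negative, median -0.53, adjusted p = 0.00624; adjusted p = 0.230 with an estimated correlation) with 0 members past the threshold over all genes or adjusted over the list alone. The regulator WRKY33 had a value of -1.31, the transporter PEN3 of -0.61 and PAD3, the last enzyme of camalexin synthesis, of -1.64. Reactive oxygen metabolism fell (15 of 22 negative, median -0.27, adjusted p = 0.00222; adjusted p = 0.230 with an estimated correlation), and adjusted over the list alone GSTF6 with -2.03 and GSTF7 with -1.91 fell. Wound and touch genes fell (16 of 19 negative, median -0.56, adjusted p = 0.00301; adjusted p = 0.230 with an estimated correlation), with 0 members past the threshold, over all genes or adjusted over the list alone.

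Seed genes fell in heavy polysomes (12 of 14 negative, median -1.38, adjusted p = 2.34e-05; adjusted p = 0.364 with an estimated correlation); adjusted over the list alone SESA2 fell. Aliphatic glucosinolate synthesis rose (14 of 20 positive, median 0.29, adjusted p = 0.04996; adjusted p = 0.394 with an estimated correlation) with 0 members past the threshold over all genes or adjusted over the list alone, and its call ended in 13 of the fits that left out 1 library. Without AtY34 heavy polysome replicate 2 the immunity list's adjusted p was 0.0795, and without wild-type heavy polysome replicate 1 that of reactive oxygen metabolism was 0.0631 and that of wound and touch genes 0.11. The seed list's was 0.0519 without wild-type heavy polysome replicate 2.

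A comparison of the lines over all fractions, added after seeing the data, gave 44 genes, 10 higher and 34 lower, with 1481 at an unadjusted p under 0.05; it treats fractions of 1 line as independent. The genes of this paragraph were chosen after their values were seen. HEI10 fell by 6.43 (SE 0.29, adjusted p = 3.29e-10) and MRD1, listed at 0 in light polysomes of the AtY34 line, was lower too (adjusted p = 2.16e-10). CYP71A12 fell by 3.53 (SE 0.31, adjusted p = 7.66e-06). Lower as well, and listed at 0 in AtY34 total RNA, were CYP82C2, another cytochrome P450 (adjusted p = 0.0183), the peroxidase PER4 and the transcription factor NAC042. GSTF6 fell by 1.70 (SE 0.20, adjusted p = 2.69e-04) and GSTF7 by 1.95 (SE 0.25, adjusted p = 9.39e-04). The germin-like GLP9 fell by 2.97, CHI of the chitinase family by 0.997, the osmotin OSM34 by 0.85 and NHL3, a gene of pathogen response, by 0.75. Higher were TAS3, a precursor of trans-acting small RNAs, which rose by 0.92 (SE 0.16, adjusted p = 0.0179), SQP1, a squalene epoxidase-like protein, by 1.25 (SE 0.22, adjusted p = 0.0182), EXO, of cell expansion, by 0.52 and ACA1, an alpha carbonic anhydrase, by 0.78. With 1 mean per line and replicate number 13 genes passed, 12 of them among the 44; of the genes of this paragraph only HEI10, MRD1, CYP71A12, GSTF6, GSTF7 and GLP9 did. Of 18 fits with 1 library left out, the call of OSM34 ended in 16, ACA1 in 15, NHL3 in 12, EXO in 11, CHI in 8, NAC042 in 5 and CYP82C2, PER4, TAS3 and SQP1 in 1 each. TPM as deposited ended the calls of CHI, OSM34 and NHL3, quantile normalization and no filter that of OSM34 and a pseudocount of 0.1 that of NAC042.

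Whether the move of a transcript between fractions differed between the lines was tested as an interaction. For heavy polysomes over total RNA 1 gene passed, AT4G35430, chosen after its values were seen: it was at 26.1, 12.8 and 19.3 scaled TPM in the 3 total RNA libraries of the AtY34 line and listed at 0 in the other 15 libraries (adjusted p = 0.00503). In this test 1022 genes had an unadjusted p under 0.05, where 1009 were due by chance. A filter at a mean of 5 scaled TPM removes it, and its call ended with only the groups compared in the fit. The smallest p-values among named genes did not pass: PFD1 had an interaction of 2.86 (SE 0.54, adjusted p = 0.372), XTH9, a cell wall enzyme, of 1.89 (SE 0.44, adjusted p = 0.731), and ELF4-L2, listed at 0 in wild-type total RNA, had an adjusted p of 0.731. Without AtY34 heavy polysome replicate 2 PFD1 passed with 3.40 (adjusted p = 0.00629).

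For heavy over light polysomes 0 genes passed (limma), with 691 at an unadjusted p under 0.05, where 1009 were due by chance. The smallest p-values belonged to PyrD (2.82, SE 0.67, adjusted p = 1), a bZIP factor (AT1G68880; adjusted p = 1) listed at 0 in heavy polysomes of wild type and EDA7 (-2.94, SE 0.76, adjusted p = 1). As lists, cell wall and growth genes had a higher heavy over light ratio in the AtY34 line (17 of 20 positive, median 0.31, adjusted p = 0.0124; adjusted p = 0.409 with an estimated correlation). The tubulin TUB5 was at 1.13, XTH9 at 0.87 and the expansin EXPA8 at 1.15, and 0 members passed the threshold over all genes or adjusted over the list alone. Indole glucosinolate and camalexin genes had a lower one (12 of 17 negative, median -0.31, adjusted p = 0.0157; adjusted p = 0.394 with an estimated correlation), and adjusted over the list alone CYP71A13 fell with -1.61. Both calls ended without wild-type heavy polysome replicate 1 or AtY34 light polysome replicate 1, the cell wall list's highest adjusted p being 0.168 and the camalexin list's 0.0902.

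Of 35 lists, 16 passed in at least 1 of the 7 comparisons, and 27 of 245 pairs of list and comparison passed; with an estimated correlation 0 pairs did. In 45 of the 245 pairs the median, the mean and the test differed in sign or the median was 0, none of them among the 27. The 19 other lists did not pass, and their smallest adjusted p was as follows. In heavy against light polysomes of wild type it was 0.0847 for the proteasome (40 members) and for TOR, autophagy and GCN2 genes (18 members, 2 of which rose over all genes and 3 adjusted over the list alone), 0.0861 for root markers, 0.216 for initiation factors, 0.238 for flavonoids and for genes with conserved upstream reading frames, 0.275 for guard cell and epidermis markers and 0.384 for iron deficiency. In heavy polysomes against total RNA of wild type it was 0.251 for elongation and release factors, 0.284 for ethylene and auxin and 0.303 for jasmonate genes. Between the lines it was 0.0582 for heat shock, 0.212 for organellar ribosomal proteins and 0.348 for phosphate starvation in heavy polysomes, 0.0847 for salicylic acid defence in light polysomes, and 0.171 for cell division and 0.191 for vascular markers in total RNA. For the interactions it was 0.238 for flower and pollen markers and 0.424 for the clock.

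For isoform use between heavy polysomes and total RNA of wild type 22 of 2972 genes passed (diffSplice, smallest adjusted p 0.00523). The count was 4 without heavy polysome replicate 3 and 55 without total RNA replicate 1. When the same libraries were regrouped, 9 of 10 splits gave at least 22 genes, the real split among them. The median of the other splits was 27, so the real grouping called no more genes than other groupings did. No gene is singled out from the 22.

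Plastid and mitochondrial loci held 33.7% ± 1.95 of TPM in total RNA, 34.9% ± 3.99 in light and 28.7% ± 4.501 in heavy polysomes of wild type, and 32.0% ± 2.24, 32.8% ± 2.67 and 29.0% ± 1.21 in the AtY34 line. In wild type heavy polysomes differed from total RNA by -4.98 percentage points (exact permutation p = 0.3, two-sided) and from light polysomes by -6.22 (exact permutation p = 0.2), and light polysomes from total RNA by 1.24 (exact permutation p = 0.7). The lines differed by -1.73 percentage points in total RNA, -2.11 in light and 0.256 in heavy polysomes (exact permutation p = 0.4, 0.6 and 1). With 3 libraries against 3 the smallest p such a test can give is 0.1. The mean shares of plastid and mitochondrial loci went opposite ways in wild type. Plastid loci held 31.8% ± 2.17 in total RNA and 26.0% ± 4.19 in heavy polysomes (exact permutation p = 0.2). Mitochondrial loci held 1.89% ± 0.228 and 2.72% ± 0.321. The mitochondrial share was not tested on its own.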

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

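The comparisons over both lines, over all fractions and between fractions of the AtY34 line were chosen after results were seen, and so were their regroupings. A difference between the lines in the change from total RNA to heavy polysomes flagged AT4G35430 (adjusted p = 0.00503), which was at 26.1, 12.8 and 19.3 scaled TPM in AtY34 total RNA and listed at 0 in the other 15 libraries. A difference between the lines in the change from light to heavy polysomes flagged the cell wall and growth list (camera adjusted p = 0.0124; adjusted p = 0.409 with an estimated correlation) and the list of indole glucosinolate and camalexin synthesis (camera adjusted p = 0.0157; adjusted p = 0.394 with an estimated correlation).

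In 58 of 100 drawn regroupings of the libraries the count for heavy over total reached the 1 gene of the real grouping, with up to 5 genes, so that grouping by chance is not ruled out for it. For heavy over light the real count was 0 genes (limma; 691 at an unadjusted p under 0.05), which 100 of 100 regroupings reach whatever the data, so the comparison tells nothing; the highest was 2. Over both lines the real counts of 191 genes for heavy polysomes against total RNA, 92 for light polysomes against total RNA and 944 for heavy against light polysomes were reached in 1 of 100 regroupings each, the real one, with at most 5, 6 and 5 genes in the others. The 44 genes that differ between the lines over all fractions were reached in 1 of 100, with at most 3 in the others. Those regroupings moved libraries within each fraction separately and so took fractions of 1 line as independent. If fractions share material, they cannot show that the count of 44 is beyond chance. With 1 mean per line and replicate number 13 genes passed.

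With 3 libraries against 3 the 10 splits are too few to show that a real count is beyond chance. The real count and the highest of the other splits were 26 and 2 in wild type for heavy polysomes against total RNA, 21 and 3 for light polysomes against total RNA and 193 and 6 for heavy against light polysomes. In the AtY34 line they were 13 and 3 for heavy polysomes against total RNA and 139 and 1 for heavy against light polysomes. Between the lines they were 16 and 10 in total RNA, 7 and 3 in light and 4 and 1 in heavy polysomes. For isoform use they were 22 and 34, and 9 of the 10 splits reached the real count, the real split among them. The median of the other splits was 27, so the isoform count was no larger than other groupings gave.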

How the results depend on the processing

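The filters on mean level, the comparisons over both lines or all fractions and those of fractions within the AtY34 line, and the differences within numbers, were chosen after results were seen; the other alternatives were set before the data were examined. Among single genes and lists 2084 values kept their direction and their side of the threshold, 513 no longer passed, 1 newly passed and 6 turned direction. Among counts and main values 293 stayed, 78 moved, 12 no longer passed and 5 turned. Of the genes named, U12 and AT2G31141 for heavy polysomes against total RNA, AT2G31141 for light polysomes against total RNA, ORA47 over both lines, HEI10 in total RNA and MRD1 in light polysomes passed under every setting, and over all fractions so did MRD1, HEI10, AtYchF1, CYP71A12, GSTF6, GSTF7, GLP9, AT1G26390 and AT2G43590. TPM hold no depth, so what depth limits could not be measured. An alternative without organellar ribosomal RNA was not run.

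With TPM as deposited the counts were 789 for heavy polysomes against total RNA and 64 for light polysomes against total RNA in wild type, 714 for heavy polysomes against total RNA in the AtY34 line, and 3579 and 1177 for these over both lines. TPM as deposited differ from the main fit only in lacking the factor per library. Without it the median of all genes moved by 0.52 for heavy and 0.45 for light polysomes against total RNA in wild type. Quantile normalization gave 15 for heavy polysomes against total RNA in wild type and 56 for light polysomes against total RNA over both lines, and the cause of these 2 counts was not tested. In TPM as deposited the Calvin cycle (adjusted p = 0.0201), cytosolic ribosomal (0.478) and light-harvesting (0.874) lists turned to higher in heavy polysomes against total RNA.

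Filters at a mean of 5, 10 and 20 scaled TPM gave 41, 41 and 65 for heavy polysomes against total RNA in wild type, and 0 each for the heavy over total interaction (limma), where 1022 genes had an unadjusted p under 0.05 before filtering; fewer genes are then tested. At 10 and 20 they gave 343 and 366 for heavy against light polysomes in wild type, 8 and 5 for the lines in total RNA, 26 and 31 for heavy polysomes against total RNA in the AtY34 line, 345 and 392 for it over both lines and 139 and 151 for light polysomes against total RNA over both lines. In the AtY34 line heavy against light polysomes gave 218, 288 and 364. At 20 light polysomes against total RNA in wild type gave 10 and the lines over all fractions 26. A pseudocount of 0.1 gave 3 for heavy over total and no filter gave 1 for heavy over light; the cause was not tested.

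With only the groups compared, and so fewer samples, the counts were 2, 2 and 0 for heavy against total, light against total and heavy against light in wild type, 1, 2 and 0 for the lines in total RNA, light and heavy polysomes, and 0 for heavy over total. They were 2 and 0 in the AtY34 line for heavy polysomes against total RNA and against light polysomes, and 94 over both lines for heavy polysomes against total RNA. AtYchF1 did not pass, with log2 fold changes of 2.291, 2.667 and 2.232 in total RNA, light and heavy polysomes, which this setting cannot change. With 1 mean per line and number 13 genes differed over all fractions, and an estimated correlation left 0 of 27 list calls.

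Numbers were not taken to pair the samples, since the labels do not say that they do. Of 18 libraries 9 correlated best with one of their own number. The median correlation was 0.00972 over 45 pairs sharing a number. It was 0.0181 over the 18 pairs sharing number and line, and -0.00422 over 90 pairs of other numbers. The organellar share hints that numbers may pair samples, with replicate 2 highest and replicate 3 lowest in 5 of 6 groups each. Within numbers heavy and light polysomes of wild type differed by -9.20, -5.67 and -3.80 percentage points and the lines in total RNA by -1.41, -1.57 and -2.22 (exact sign-flip permutation p = 0.25 each, the smallest that 3 differences can give). With the number as a block the lines in light polysomes gave 4 genes, GSTF7 and AT1G26390 not among them, and with number and line as a block heavy polysomes against total RNA in wild type gave 45 and heavy over total 0; other block counts stayed within 1.5 times.

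Leaving out a library gave 17 (without wild-type total 3) to 30 genes for heavy polysomes against total RNA, 7 (without light 3; 13 without light 1) to 26 for light polysomes against total RNA, and 67 to 124 for heavy against light polysomes in wild type, where all 6 libraries moved the count by over 1.5 times. Between the lines it gave 16 to 23 in total RNA, 3 (without AtY34 light 2; 4 without wild-type light 3) to 9 in light polysomes and 3 to 8 (without AtY34 heavy 2) in heavy polysomes. It gave 1 to 3 for heavy over total (2 without wild-type total 3, 3 without AtY34 heavy 2), and 0 to 1 for heavy over light (1 without wild-type light 1 or 2, wild-type heavy 2 or AtY34 heavy 3). In the AtY34 line it gave 7 (without total 3) to 37 (without heavy 2) for heavy polysomes against total RNA and 48 to 144 for heavy against light, where only heavy 2 left the count. Over both lines it gave 112 (without AtY34 total 3; 122 without wild-type total 1) to 187 for heavy polysomes against total RNA. It gave 36 to 92 for light polysomes against total RNA (lowest without wild-type light 1; also moved by wild-type total 3 and light 3, AtY34 total 1 and light 3) and 599 (without wild-type light 3) to 879 for heavy against light. Over all fractions it gave 20 to 40 (lowest without AtY34 heavy 3; also moved by wild-type light 3, heavy 1 and heavy 3 and AtY34 light 1 and 2). AtYchF1 ran from 2.106 to 2.456, 2.388 to 2.911 and 2.147 to 2.363, list calls from 21 to 29 and isoform calls from 4 to 55. The cause was not tested.

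The organellar share without a library differed by -7.44 to -3.03, -0.944 to 2.96 and -8.68 to -4.04 percentage points in wild type for heavy against total, light against total and heavy against light, and between the lines by -2.88 to -0.650, -3.83 to 0.0781 and -1.69 to 2.72 in total RNA, light and heavy polysomes. It turned without wild-type light 2 (-0.944 and 0.0781) and, in heavy polysomes, without wild-type heavy 1 or 3 or AtY34 heavy 1 (-1.69, -0.256 and -0.265). The heavy over total interaction of AtYchF1 ran from -0.2237 to 0.1256 and turned to 0.1256, 0.07279 and 0.05186 without wild-type total 2, wild-type heavy 3 and AtY34 total 1, never passing. The cause was not tested.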

Other observations

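The tests of the patterns below were chosen after the patterns were seen. Non-coding RNA other than ribosomal, small nuclear and long non-coding RNA held 17.2% ± 1.31 of TPM in wild-type total RNA, 2.41% ± 0.780 in light and 0.609% ± 0.136 in heavy polysomes (n = 3), and AT1G15405 alone held 15.8%, 18.4% and 16.8% in the 3 total RNA libraries. Small nuclear RNA held 0.680% ± 0.226, 0.131% ± 0.0311 and 0.0812% ± 0.0597, and protein-coding genes 44.4% ± 2.88, 56.7% ± 4.12 and 63.2% ± 5.74. The ribosomal locus AT3G41768 ranged from 758 to 51274 TPM between libraries. Wild-type total RNA replicate 3 lay at 111 on the second principal component of all genes, against 30.05 and 28.1 for the other wild-type total RNA libraries.

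HEI10 and its neighbour MRD1 were nearly absent from the AtY34 line, and no biological explanation was tested other than a change of the chromosome at these loci. Loss or silence of a wider stretch of the chromosome does not account for it, since the 3 nearest tested genes on each side had a median log2 fold change of -0.0283 over all fractions, with MSL4 at -0.51, MUM4 at -0.24 and MPK18 at 0.34. A different split of reads between the overlapping loci does not either: the sum of both was lower in every AtY34 library in 3 of 3 fractions, at 4.56 against 525 scaled TPM in total RNA. AT1G53490 was above 0 in 9 of 9 AtY34 libraries, at 1.38 to 10.8 TPM as deposited, and AT1G53480 in 2 of 9. If both loci were lost from the genome, reads shared between them could not give these values. Loss of both loci stays open, since it was not excluded that reads from elsewhere were counted to AT1G53490.

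Short genes were lower in heavy than in light polysomes: among protein-coding genes with a mean of at least 20 scaled TPM, in wild type 172 genes with a span under 750 bp had a median log2 fold change of -0.38, and 147 genes of 5000 bp or more 0.31. Protein-coding genes called in wild type had a median span of 1504 bp if lower and 1832 bp if higher. Both lay below the 2364 bp of all tested ones, so the genes called higher were not long. Over 19514 genes of any level the separate AtY34 libraries showed a weak trend, with a rho of 0.211 between span and log2 fold change. A longer reading frame that holds more ribosomes would give such a trend. Spans include introns, and reading frames were not measured. Genes near the detection floor do not account for the trend, as that rho was 0.246 among the 4164 genes with a mean of at least 20 scaled TPM. Short transcripts were not lower in light polysomes than in total RNA, as the rho of span there was no higher than -0.0666. Poor recovery from the gradient stays open, since a loss of short transcripts in heavy polysomes alone would not show in that comparison.

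Some genes with a role in stress or defence, CYP71A12, GSTF6, GSTF7 and GLP9, picked after their values were seen, were lower in the AtY34 line over all fractions. Of the lists set beforehand, salicylic acid defence (smallest adjusted p 0.0847) and jasmonate genes did not pass. Immunity and camalexin synthesis passed as lower in heavy polysomes and not in total RNA or light polysomes. Aliphatic glucosinolate synthesis passed as higher in heavy polysomes. Reactive oxygen metabolism passed as lower in all 3 kinds of RNA. Its calls ended in light polysomes without AtY34 replicate 2 and in heavy polysomes without wild-type replicate 1. None of these lists passed with an estimated correlation. The camalexin list holds CYP71A12 and the reactive oxygen list GSTF6 and GSTF7, so they are not separate support for the picked genes. Scaling of TPM does not account for the falls of these genes, since the mean log2 scaling factors of the lines differed by 0.0517 and the genes fell by 1.70 or more, and neither does a different split of reads between GSTF6 and GSTF7, whose sum was lower in every AtY34 library in 3 of 3 fractions. A lower share of roots in the AtY34 seedlings stays open, with a median of 0.477 for root markers in total RNA. The difference between the lines in the median of these markers per library was 0.296, with a 95% interval of ± 0.544 from the spread between libraries. Wounding or touch at harvest that differed between the lines stays open as well: the median of the wound and touch list in total RNA was 0. The difference between the lines in the list's median per library was -0.179 there, with a 95% interval of ± 0.394. In light and heavy polysomes that list fell. Which gene the AtY34 line changes first was not tested.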
